A study of Capra hircus with 11 samples.

How the data were processed

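Small RNA libraries were sequenced from the omental adipose tissue, the fat of the abdominal fold hanging from the stomach, of 11 lactating Alpine goats (Capra hircus). Per the labels, 5 goats had free access to the standard diet until slaughter and 6 were deprived of feed for the last 48 h. Each library came from a separate goat, so the spread within a group is between animals. The labels give no batch, pairing or animal covariate, and replicates were numbered within each group in accession order, which pairs nothing.

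Per the labels' protocols, total RNA was extracted with a phenol reagent and a small RNA kit, libraries were made with the TruSeq Small RNA kit with 13 cycles of PCR, products of 140 to 160 nt were cut from a gel, and single reads of 50 bases were taken on an Illumina HiSeq sequencer. This kit adds no molecular identifier that the labels mention, so reads are not independent molecules, and every counting interval given covers counting error only. Ligation of adapters favours some small RNA sequences over others. Shares of reads therefore rank miRNAs within this protocol and are no molar amounts, whereas a comparison of one miRNA between groups is less exposed to that bias. Trimming, aligner, miRNA database version, genome build and normalization tool are not given in the sources used here.

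The authors deposited a list of mature miRNAs with one normalized signal per miRNA and library. All names carry the bovine prefix, left out here, so goat sequences that differ from the bovine ones could be undercounted, and members of one family that differ by few bases may share reads. Each library lists 637 miRNAs, except feed-deprived replicate 1, which lists 629. In every library 100% of the non-zero deposited signal values were whole multiples of the smallest non-zero value, within a tolerance of 0.001 read. The deposited signal is therefore a whole read count divided by 1 factor per library. The value of 1 read ran from 0.607 to 1.33, and the recovered factors matched DESeq2's median-of-ratios factors computed from these reads within ratios of 0.997 to 1.001. Recovered depth was 16974441 to 25389788 miRNA reads per library.

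All computing was done in R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0. The 629 miRNAs listed in all 11 libraries were filtered with edgeR's filterByExpr at a minimum count of 10 on the recovered reads, which left 360. The deposited signal was taken as log2(value + 1), the pseudocount being 1, and compared with limma, with a variance trend and robust moderation, two-sided. Benjamini-Hochberg adjusted p under 0.05 over the 360 miRNAs was the threshold. Fold changes are on the log2(value + 1) scale, which understates the change of miRNAs with few reads. The plan made before the data were examined was edgeR's quasi-likelihood test for counts, with limma if the values were normalized. Since the values were normalized, limma was the test, and edgeR on the recovered reads was an added alternative, as were other pseudocounts, TMM factors, a fit with no variance trend, and the 8 miRNAs of the shorter list.

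Before the data were examined 18 lists of miRNAs were fixed: adipogenesis, lipid and insulin signalling, brown fat, 4 families (the miR-15/16 list also holding the neighbouring miR-450 and miR-542), 2 genomic clusters, and markers of other cell types. They matched 194 listed miRNAs, of which 157 were tested. The 16 lists with at least 3 tested members were compared with the other miRNAs by limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 16. The smooth muscle and pericyte list, with 2 tested members, and the liver list, with 1, were not tested. Beside camera stand camera with an estimated correlation, fry, which asks only whether a list's members move one way, and, chosen after seeing the data, an exact permutation test of the list mean over all 462 splits of the libraries. Separation of whole profiles was tested by a distance-based permutation test on Euclidean distances, exact over the 462 splits, and 5 measures of library composition by exact two-sided permutation tests. The plan named log2 CPM with TMM factors for the list and profile tests. Both used log2(value + 1) instead, and log2 CPM became an alternative. Within groups the libraries had Spearman correlations of 0.950 to 0.968. The closest pair within a group differed by a chi-square of 661 per degree of freedom, so no library was a copy of another of its group. Pairs across the groups were not compared this way.

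The rule for naming miRNAs, fixed before the data were examined, took those past the threshold with a mean of 10 CPM or more in a group. It also took the smallest p-values up to 10 in all and the 10 most abundant. Up to 4 members of each list with the smallest p, and members of lists that passed, were added. miR-431 and miR-541 had means under 10 CPM in both groups and entered through the smallest p-values. The rule was narrowed after values were seen: 2 members for lists that did not pass, and for lists that passed, the first 4 with any others under an unadjusted p of 0.05. All leukocyte and erythrocyte members were named, which gave 59 miRNAs. The test steps were checked on 20 simulated sets of 360 miRNAs with 60 changed. Of the changed miRNAs 60.2% were recovered at a fold of 2 and 94.7% at a fold of 4, and 4.50% of calls were unchanged miRNAs. With no change simulated, the mean number of calls was 0. The simulated miRNAs varied independently of each other, so these figures do not cover the list tests. With 60 changed miRNAs the adjusted threshold is also easier to reach than with few, so the recovery may be lower in these data.

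Alternatives covered the scaling, the filter, the test, the threshold, reads thinned to the smallest library, the most abundant miRNA left out, and each library left out in turn. Leaving out a library was run in 2 versions. The first reran the low-count filter in each fit. After it was seen to drop miR-431 before testing in 5 of the 11 fits, a second version kept the 360 miRNAs in every fit. That second version is more favourable to miR-431, and both are reported. Neighbouring miRNA genes were looked up in the goat gene table of assembly ARS1.2, in which 253 of 584 listed miRNA stems were found, and it was used for no coordinates. Target genes and mRNA levels were not analysed here.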

Results

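The miRNAs of omental fat were profiled in goats at the peak of lactation, 48 ± 2 days after kidding, a stage at which body fat is heavily drawn on for milk. After 2 weeks on a hay diet of 35% forage and 65% concentrate, 5 control goats kept eating and 6 were deprived of feed for 48 h. The comparison asks how a short and complete loss of feed intake changes the miRNAs of a fat depot. The libraries held 16974441 to 25389788 miRNA reads. Depth differed between the groups by less than the spread between goats (exact permutation p = 0.258).

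A few miRNAs made up most of the reads in both groups. miR-143, an abundant miRNA of mesenchymal tissue, took 26.6% ± 4.88 of the reads in controls (SD, n = 5) and 25.8% ± 3.52 after feed deprivation (SD, n = 6). miR-10b followed with 18.7% ± 1.84 and 16.4% ± 2.86. miR-26a held 11.97% ± 2.31 and 12.7% ± 3.86, and miR-10a 8.45% ± 1.23 and 7.98% ± 0.947. The rest of the 10 most abundant were miR-22-3p at a mean of 4.09% over all libraries, miR-27b at 2.93%, miR-30a-5p at 2.91%, the endothelial miR-126-5p at 2.38%, miR-148a at 2.27% and miR-191 at 1.58%. None of these 10 passed the threshold in limma, and their log2 fold changes lay between -0.36 (miR-10b, limma adjusted p = 0.423) and 0.07 (miR-191, limma adjusted p = 0.938). With library totals as the only scaling, miR-26a, miR-22-3p, miR-27b, miR-126-5p and miR-148a had small positive values, and with upper-quartile factors miR-191 had a negative one. Leaving out 1 library moved miR-191 between 0.0066 (without feed-deprived replicate 4) and 0.16 (without feed-deprived replicate 5).

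The makeup of the libraries did not differ detectably. The 10 most abundant miRNAs took 81.6% ± 0.855 of reads in controls and 79.6% ± 3.50 after feed deprivation, and 499.6 ± 10.5 and 511.5 ± 15.1 miRNAs had at least 1 read. Exact permutation tests of the 5 composition measures gave adjusted p-values of 0.346 to 0.766. Whole profiles did separate: the split by feeding held 18.3% of the squared distance between libraries (distance-based permutation test, exact p = 0.0022, the smallest that 462 splits can give). Other splits of the goats also hold some share, so 18.3% is no estimate of the part due to feeding. The first principal component, with 22.4% of the variance, also differed between the groups (exact p = 0.0043).

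**Figure D1:**
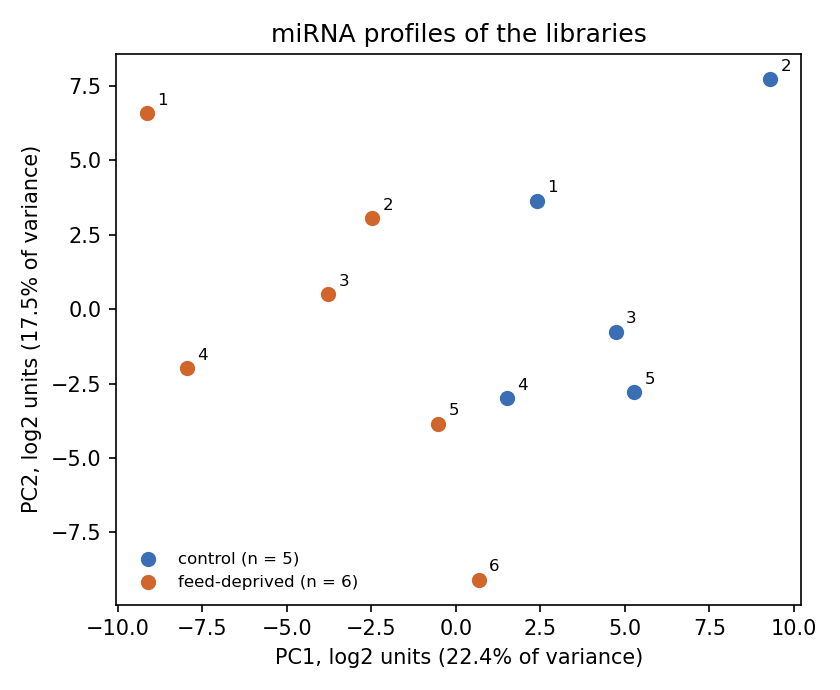
Scores of the 11 libraries on the first and second principal components of log2(value + 1) over 360 miRNAs, in log2 units, with the replicate number beside each point. Feed-deprived goats lie at PC1 scores of -9.13 to 0.675 and controls at 1.51 to 9.30, and the second component (17.5% of variance) does not part the groups (exact p = 0.580).

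Feed deprivation raised 3 of the 360 tested miRNAs, miR-431, miR-541 and miR-142-5p, and lowered 0. miR-431, encoded in the imprinted DLK1-DIO3 region, was close to undetected in controls, at 1.34 ± 1.05 normalised reads (SD, n = 5), and reached 18.5 ± 12.4 after feed deprivation (SD, n = 6). Its log2 fold change was 2.99 ± 0.476 (SE, limma adjusted p = 0.0088). miR-541, from the same region, rose from 8.21 ± 4.20 to 50.5 ± 32.4 normalised reads, a log2 fold change of 2.41 ± 0.458 (SE, limma adjusted p = 0.025). miR-142-5p, a miRNA of blood-forming cells, rose from 16568 ± 2858 to 28704 ± 5802 normalised reads, a log2 fold change of 0.79 ± 0.164 (SE, limma adjusted p = 0.037). For each of the 3, all 6 feed-deprived goats lay above all 5 controls.

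miR-431 and miR-541 rested on few reads. Controls held 0 to 2 reads of miR-431 per library, 6 in all, against 8 to 69 in feed-deprived goats, 139 in all, a ratio of normalised rates of 15.6 with an exact 95% counting interval of 6.97 to 43.1. For miR-541 the totals were 38 and 350 reads, a ratio of 6.18 with an interval of 4.42 to 8.89. miR-142-5p had 11699 reads or more in every library, and its ratio was 1.74. limma counted 42 miRNAs at an unadjusted p under 0.05. On the recovered reads edgeR called the same 3 miRNAs and 0 lower, DESeq2 called 9 higher and 0 lower, and voom called 3 higher and 1 lower. No miRNA passed in limma when only the 190 miRNAs with a mean of 10 CPM or more were tested, a filter that removes miR-431 and miR-541.

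The calls also depended on single goats, shown first with the filter rerun in each fit. miR-541 no longer passed without feed-deprived replicates 1, 4 or 5 or without control replicates 2, 3 or 5, with limma adjusted p-values up to 0.101, while its log2 fold change stayed between 2.12 and 2.64. It was also lost in voom with sample weights (limma adjusted p = 0.075). miR-142-5p no longer passed without feed-deprived replicates 1, 2, 4 or 5 or without control replicates 2 to 5, again up to 0.101, while its log2 fold change stayed between 0.70 and 0.85. With all libraries it was lost in 5 settings, with limma adjusted p-values of 0.095 (upper-quartile factors), 0.055 (no filter), 0.053 (a mean of 10 CPM or more), 0.099 (no variance trend) and 0.075 (voom with sample weights). When the filter was rerun in each fit, miR-431 was dropped before testing without any 1 of feed-deprived replicates 1 to 5 and passed in the other 6 fits. The number of higher miRNAs was then 0 without feed-deprived replicates 1, 4 or 5, and 1 without feed-deprived replicate 2 or control replicates 2, 3 or 5. With the 360 miRNAs kept in every fit, a version chosen after seeing the first, miR-431 passed in all 11 fits, with limma adjusted p-values of 0.0037 to 0.041, and the lowest number of higher miRNAs was 1. In that version miR-541 was lost in the same fits as before, with limma adjusted p-values up to 0.080. The fits that lost miR-142-5p were also the same, except that it passed without feed-deprived replicate 2, and its limma adjusted p-values reached 0.088.

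The next miRNAs in order of p did not pass. miR-2285bb, of a large ruminant family, had the only negative value among the 10, at 268 ± 229 normalised reads in controls and 44.0 ± 59.1 after feed deprivation, a log2 fold change of -3.05 (limma adjusted p = 0.063), with 5 of 6 feed-deprived goats below all controls. It passed as lower without feed-deprived replicate 6 (limma adjusted p = 0.0037), with upper-quartile factors, with library totals and in both voom fits. miR-1260b had a log2 fold change of 1.44, miR-665 of 1.46 and miR-223, a miRNA of neutrophils and other myeloid cells, of 2.12 (limma adjusted p = 0.074 for each). miR-543 at 1.34 and miR-132 at 1.15 had a limma adjusted p of 0.093, and miR-1247-5p at 1.38 had 0.198. These 6 with higher values were the miRNAs that DESeq2 called in addition. All 6 feed-deprived goats lay above all controls for miR-665 and miR-132, and 4 or 5 of them for the rest. miR-223 passed in limma without control replicate 1 (limma adjusted p = 0.022) and miR-1260b without feed-deprived replicate 6 (limma adjusted p = 0.024). With library totals as the only scaling miR-665 (limma adjusted p = 0.025), miR-223 (0.038), miR-1260b (0.038) and miR-543 (0.042) passed.

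**Figure D2:**
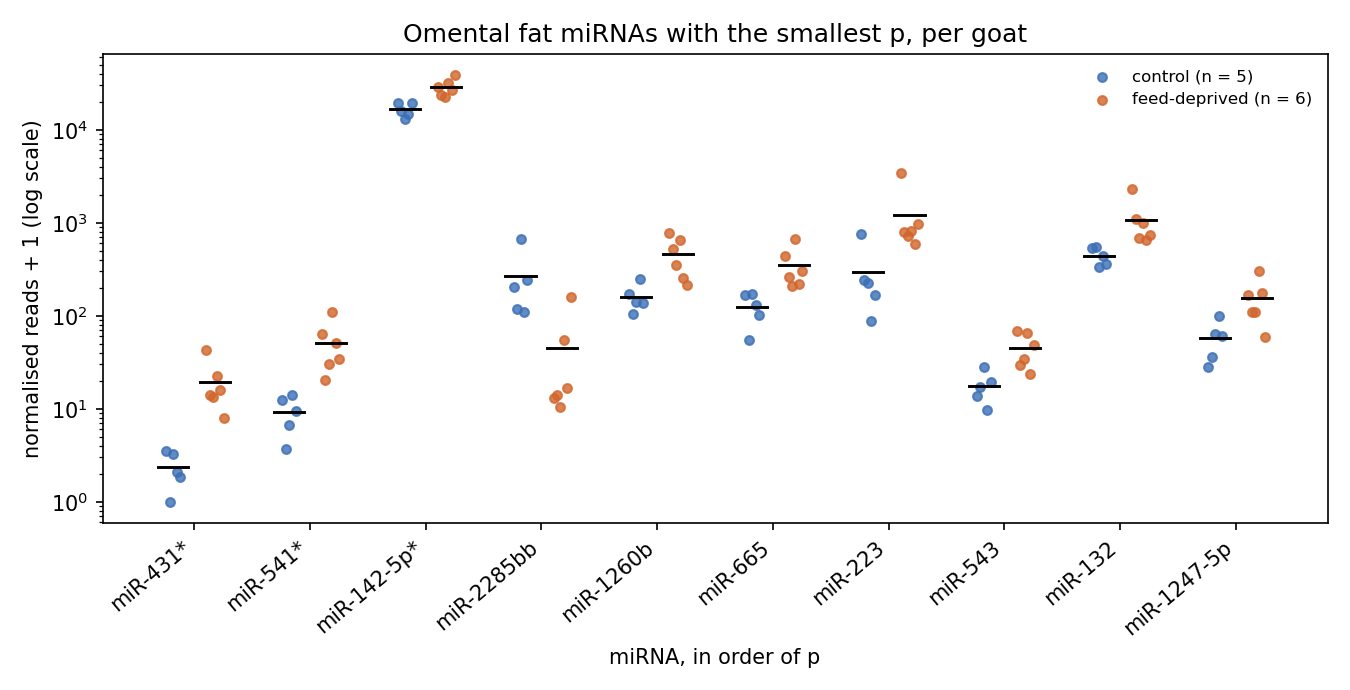
Normalised reads plus 1 on a log axis for the 10 miRNAs with the smallest p in limma, 1 point per goat (5 control, 6 feed-deprived), with the arithmetic group mean as a bar and an asterisk on the 3 that passed. miR-431 runs from 0 to 2.55 normalised reads in controls and from 6.98 to 41.9 after feed deprivation, with no overlap.

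Most tested members of the DLK1-DIO3 cluster, the large imprinted group of miRNAs expressed from the maternal chromosome, had higher values, though its most abundant members changed little. Of 58 members matched, 36 were tested. Of these 36, 32 had a positive log2 fold change, with a median of 0.46 and a mean of 0.60, and camera called the list higher (adjusted p = 1.1e-08). The call was lost with an estimated correlation (adjusted p = 0.390), in fry (adjusted p = 0.133) and in the exact permutation test of the list mean (p = 0.0087, adjusted p = 0.087). Over all miRNAs 2 members passed, and 5 adjusted over the list alone: miR-431, miR-541, miR-665, miR-543 and miR-1247-5p. Among those that did not pass either way, miR-410 went from 399 ± 93.1 to 692 ± 252 normalised reads (log2 fold change 0.75), miR-487a from 10.9 ± 2.25 to 24.3 ± 12.7 (0.96) and miR-370 from 19.1 ± 9.41 to 35.9 ± 11.5 (1.03, and 0.59 without control replicate 2). miR-493 had a log2 fold change of 0.75, miR-495 of 0.72 (0.44 without control replicate 4) and miR-487b of 0.47. The other 25 tested members ran from -0.29 to 0.82. Among them were the tested members with the most reads in controls. Of these, miR-411a, at 17599 ± 4662 normalised reads in controls, had a log2 fold change of 0.23. The next in abundance were miR-379 (0.09), miR-136 (0.22), miR-409a (-0.14) and miR-380-3p (0.11). The abundant miR-127, untested because 1 library does not list it, had a log2 difference of 0.0082 over the libraries that do. Of the 36 members 27 were found in the goat gene table of assembly ARS1.2, all 27 on 1 chromosome within a run of 44 neighbouring miRNA genes. Across the other scalings 27 (upper quartile) to 35 (library totals) members were positive.

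Leukocyte miRNAs also had higher values, all 9 of them. The list mean was 0.62 and the median 0.40 on the log2 scale (camera adjusted p = 3.6e-04). The call was lost with an estimated correlation (adjusted p = 0.265), in fry (adjusted p = 0.058) and in the exact permutation test of the mean (p = 0.011, adjusted p = 0.087). miR-142-5p passed over all miRNAs, and miR-142-5p and miR-223 adjusted over the list alone. miR-223 stood at 294 ± 264 normalised reads in controls and 1222 ± 1102 after feed deprivation, where replicate 1 alone had 3458. miR-142-3p, from the other arm of the miR-142 hairpin, had a log2 fold change of 1.02 (limma adjusted p = 0.394), and 0.66 without control replicate 2. miR-155, induced in activated immune cells, had 0.40, miR-147 had 0.46, and miR-150, abundant in lymphocytes, had 0.35, and 0.19 without control replicate 5. miR-146b at 0.26 (0.08 to 0.46 without 1 library), miR-342 at 0.12 (0.04 to 0.19) and miR-146a at 0.08 (-0.05 to 0.20) were nearest to 0, and miR-342 and miR-146a had negative values with upper-quartile factors. Markers of red blood cells went the same way: miR-144 had a log2 fold change of 0.85, miR-451 of 0.62 and miR-486 of 0.17, the last negative with upper-quartile factors. That list did not pass with all libraries (camera adjusted p = 0.176) and passed without control replicate 3 (camera adjusted p = 0.016).

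The miR-17-92 clusters, linked to cell proliferation, were the last list that passed in camera (adjusted p = 0.011), with 12 of 13 members positive and a mean of 0.31. The call was lost with an estimated correlation (adjusted p = 0.427), in fry (adjusted p = 0.133), in the exact permutation test of the mean (adjusted p = 0.213), at a mean of 10 CPM or more (adjusted p = 0.050) and without control replicate 2 (adjusted p = 0.082). Its largest changes by p were in miR-20a, from 646 ± 145 to 963 ± 201 normalised reads (log2 fold change 0.58), and miR-17-5p, from 864 ± 141 to 1281 ± 379 (0.54). miR-17-3p had 0.43 (0.25 without control replicate 2) and miR-19a 0.31. None of the 13 passed, over all miRNAs or adjusted over the list alone. With upper-quartile factors 10 of the 13 were positive.

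**Figure D3:**
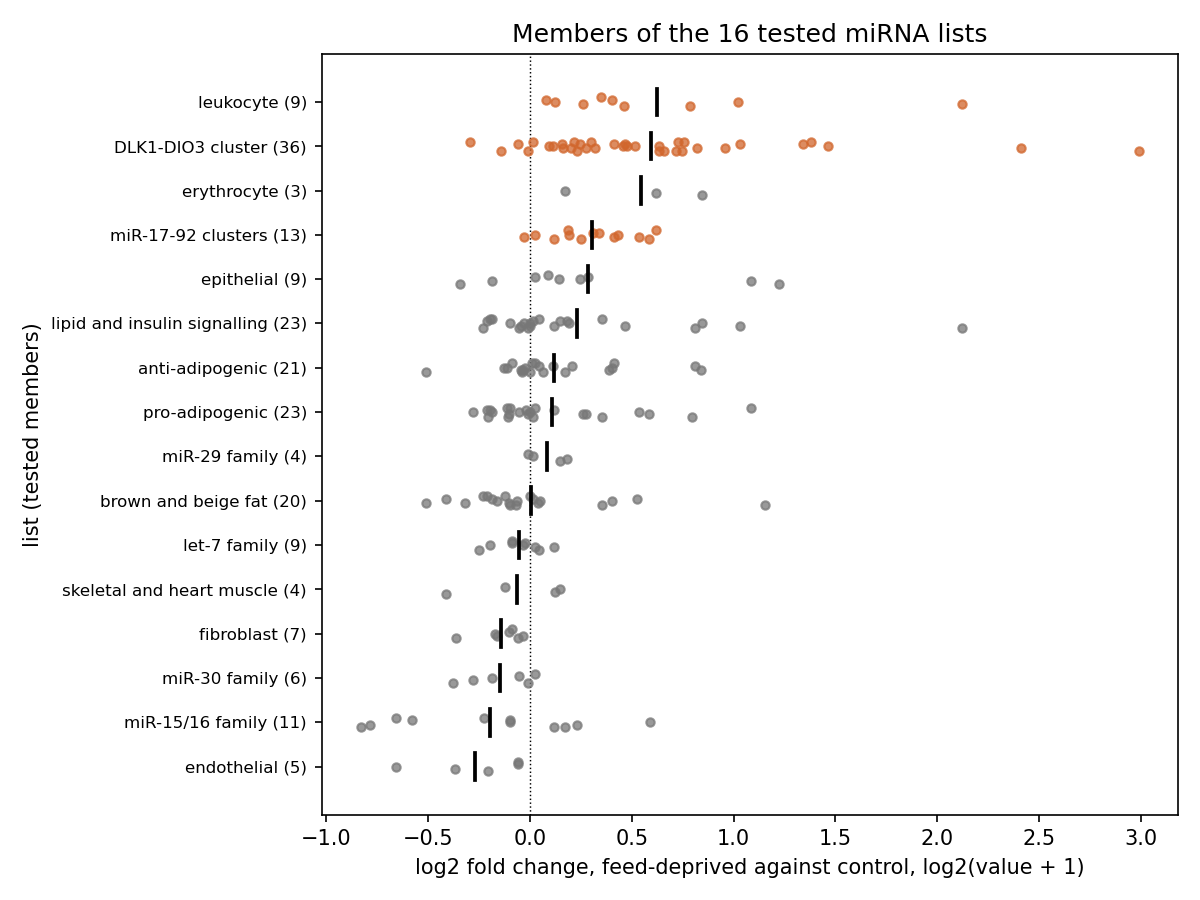
Log2 fold change of feed-deprived against control goats, on the log2(value + 1) scale, for each tested member (point) of the 16 tested lists, with the list mean as a bar and the tested members in brackets. The 3 lists called by camera at the preset correlation are orange: leukocyte (mean 0.62), DLK1-DIO3 cluster (0.60) and miR-17-92 clusters (0.31), and each of these calls is lost with an estimated correlation.

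The lists tied to fat cell formation and lipid handling did not pass. Of 23 pro-adipogenic miRNAs 11 were higher and 12 lower, with a median of -0.01, a mean of 0.11 and camera adjusted p = 0.741. miR-21-5p, one of the most studied miRNAs of fat and fibrosis, led them with 134550 ± 43611 normalised reads in controls and 234660 ± 78396 after feed deprivation, a log2 fold change of 0.80 that did not pass (limma adjusted p = 0.218). Of 21 anti-adipogenic miRNAs 13 were higher and 8 lower (camera adjusted p = 0.739). The lowest p there belonged to miR-193b at -0.51 (limma adjusted p = 0.258), followed by miR-130b at 0.84. The lipid and insulin signalling list had 14 higher and 9 lower of 23 (camera adjusted p = 0.429), and miR-223, which it shares with the leukocyte list, was its 1 member past the threshold adjusted over the list alone. The brown and beige fat list had 8 higher and 12 lower of 20, with a mean of 0.0037, a median of -0.08 and a downward camera direction (adjusted p = 0.6253). miR-196b led it at 1.15 and miR-193b followed. The counts of these 4 lists moved with the scaling. With library totals 18 of 23 pro-adipogenic, 20 of 21 anti-adipogenic, 19 of 23 lipid and insulin and 14 of 20 brown and beige fat miRNAs were positive, against 7, 6, 8 and 4 with upper-quartile factors.

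None of the 4 family lists passed. The let-7 family had 3 higher and 6 lower of 9 (camera adjusted p = 0.623), led by miR-98 at -0.25 and let-7g at 0.12. Of 6 miR-30 miRNAs 5 were lower (camera adjusted p = 0.249), led by miR-30f at -0.38 and miR-30b-5p at -0.28. The miR-29 family had 3 higher of 4 (camera adjusted p = 0.741), with miR-29a at 0.15 and miR-29b at 0.18. In the miR-15/16 list 7 of 11 were lower (camera adjusted p = 0.249). Its lowest p-values belonged to miR-450a at -0.83 and miR-542-5p at -0.78, which are genomic neighbours of miR-424 and do not share the seed of the family. Several of these values were smaller, or of the other sign, without 1 control: miR-30b-5p was -0.05 and let-7g 0.07 without replicate 5, miR-98 -0.13 without replicate 1, and miR-29a 0.08 and miR-29b -0.11 without replicate 2. These signs shift with the scaling, since upper-quartile factors move the median of all miRNAs to -0.17 and library totals to 0.16, against 0.00397 for the deposited factors. With library totals 7 of the 9 let-7 miRNAs and 3 of the 6 miR-30 miRNAs were positive, and with upper-quartile factors 3 of the 4 miR-29 miRNAs were negative.

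Markers of the other cell types of fat tissue did not pass. All 5 endothelial miRNAs were lower, with a mean of -0.27 (camera adjusted p = 0.168), among them miR-126-3p at -0.20 and miR-218 at -0.37 (-0.22 without feed-deprived replicate 1), and so were all 7 fibroblast miRNAs, with a mean of -0.14 (camera adjusted p = 0.176), led by miR-10b and miR-152. With library totals 3 of the 5 and 2 of the 7 were negative. Of 9 epithelial miRNAs 7 were higher (camera adjusted p = 0.442), led by miR-215 at 1.22, which was 0.56 without feed-deprived replicate 2, and miR-375 at 1.09, which was 0.64 without feed-deprived replicate 6. The muscle list had 2 higher and 2 lower of 4 (camera adjusted p = 0.751). Its miR-133b was at -0.41 (-0.09 without control replicate 3) and its miR-499 at 0.13 (0.03 without feed-deprived replicate 5). miR-499 was negative with upper-quartile factors.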

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

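Of the tests in this part, the comparison of miRNAs within libraries was chosen after the result was seen. Among 128 sets of values examined for a goat far from the rest of its group, 6 had one, and chance alone gives about 1 in 20. Feed-deprived replicate 1 stood above its group for miR-223, at 3458 normalised reads against 595 to 963 in the other 5, and for miR-130b, at 950 against 381 to 518. Control replicate 2 had 3.99 normalised reads of miR-370 against 18.4 to 28.1 in the other controls. Feed-deprived replicate 5 was low for miR-19a, at 422 against 486 to 518, and high for miR-499, at 93.4 against 58.7 to 69.0. Control replicate 5 had 7561 normalised reads of miR-152 against 3625 to 3950.

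The higher leukocyte miRNAs may come from more immune cells of every kind in the fat, from more blood left in it, or from a change in some immune cells. Chance stays open as well, since 31 of 100 splits of the goats gave at least the 3 lists of the real one. If all leukocytes had increased alike, miR-150 of lymphocytes should go up about as much as miR-142-5p. Its upper 95% limit, 0.744 on the log2 scale, lay just under the 0.79 of miR-142-5p, a bound written in advance as arguing against that account. That bound left out the error of miR-142-5p itself, with limits of 0.43 to 1.14. Taken within libraries, the difference of 0.44 had an exact permutation p of 0.134, so the account stays open. Over all 11 comparisons of miR-142-5p with the other leukocyte and erythrocyte miRNAs, none passed (exact permutation, adjusted p = 0.107 to 0.909). The smallest p-values were for miR-342 (difference 0.67, exact p = 0.013) and miR-146a (0.71, exact p = 0.019). A first set of 5 comparisons had given these 2 an adjusted p of 0.049. That first set held miR-342, miR-146a and miR-486, the members nearest to 0, with miR-150 and miR-451. Because of those nearest members it was widened to all 11, so it decides nothing. Residual blood stays open too, since the upper limit of miR-451, the main red cell miRNA, was 1.36.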

How the results depend on the processing

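No paired analysis was possible because replicate numbers follow accession order. Collapsing repeated names was not run, since no name occurred more than once. Alternatives chosen after seeing the data were TMM factors in limma, pseudocounts of 0.5 and 5, no variance trend and the 8 added miRNAs. So were the exact permutation of list means and the fits without 1 library that kept the 360 miRNAs. edgeR with TMM had been planned as the main test for counts, and log2 CPM with TMM as the main scale for lists and profiles. Both were run as alternatives on the recovered reads. Of 2338 values of named miRNAs under alternatives, 2251 kept direction and side of the threshold, 33 lost the threshold, 20 gained it and 34 changed sign. Most of these miRNAs had not passed, so keeping their side shows little. Only the 3 that passed could lose the threshold, and the 33 losses were all of miR-541 and miR-142-5p. Among alternatives with all libraries miR-541 passed in 16 of 17 and miR-142-5p in 13 of 18. Without 1 library they passed in 5 and 3 of 11 fits with the filter rerun, and in 5 and 4 with the 360 kept. Of 271 list values these counts were 250, 11, 1 and 9, and only the 3 lists that passed could lose the threshold. Separation by feeding kept its side under every alternative run. miRNAs with few reads limit depth: miR-431 had at most 2 reads in a control.

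Higher miRNAs numbered 3 and lower ones 0. There were 7 and 1 with library totals only, 0 higher at a mean of 10 CPM or more, 9 higher in DESeq2, 1 and 1 in voom with sample weights, and 8 and 1 at an adjusted p threshold of 0.1. There were 2 higher and 1 lower with upper-quartile factors, 3 and 1 in voom, and 2 higher with no filter or no variance trend, miR-142-5p being lost in these fits except voom. Without 1 library, higher miRNAs ran from 0 to 4 and lower ones from 0 to 1 when the filter was rerun, and from 1 to 4 and 0 to 1 with the 360 kept. The 0s came partly from the filter, which then left miR-431 untested. Lists higher fell from 3 to 0 with an estimated correlation, 0 in fry and 0 in exact permutation. For all other changes the cause was not tested.

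Log2 fold changes that changed sign with upper-quartile factors were miR-191 (-0.11), let-7g (-0.061), miR-29a (-0.031), miR-499 (-0.052), miR-342 (-0.058), miR-146a (-0.099) and miR-486 (-0.0057), and with library totals miR-26a (0.060), miR-22-3p (0.052), miR-27b (0.12), miR-126-5p (0.11), miR-148a (0.051) and miR-152 (5.7e-04). miR-191 was -0.014 in voom with sample weights. Without 1 library, in both versions, sign changes came in miR-26a without feed-deprived replicate 1 (range -0.25 to 0.046), miR-27b without feed-deprived replicate 1 (0.018) or control replicate 3 (0.062; lowest -0.12), miR-126-5p without control replicate 4 (-0.093 to 6.4e-05), miR-29b without control replicate 2 (-0.11 to 0.40), miR-152 without control replicate 5 (-0.22 to 0.041), miR-486 without control replicate 5 (-0.060 to 0.35), and miR-146a without feed-deprived replicate 5 (-0.00128) or control replicates 3 (-0.00125) or 5 (-0.048; highest 0.20). Lists that turned direction without passing were brown and beige fat in exact permutation (adjusted p = 0.974) and the pro-adipogenic list at a mean of 10 CPM or more (camera adjusted p = 0.928). Without 1 library, camera adjusted p ran from 0.527 to 0.942 for the pro-adipogenic list, 0.441 to 0.943 for the anti-adipogenic, 0.292 to 0.951 for let-7, 0.408 to 0.900 for miR-29 and 0.381 to 0.989 for muscle, each turning direction in at least 1 fit. The difference in the percent of reads in miR-143 ran from -2.32 to 1.08, the latter without control replicate 3.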

Other observations

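Of the tests in this part, the comparison of hairpin arms with other splits and the exact permutation of list means were chosen after the result was seen, and so were miR-212, miR-99b, miR-100 and miR-592.

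Some miRNAs outside the rule for names also had low p-values without passing. miR-212, processed from one primary transcript with miR-132, went from 69.8 ± 23.8 normalised reads in controls (SD, n = 5) to 173 ± 108 after feed deprivation (SD, n = 6), a log2 fold change of 1.12 (limma adjusted p = 0.289). The related miR-99b and miR-100, both abundant, had log2 fold changes of -0.45 (limma adjusted p = 0.252) and -0.44 (limma adjusted p = 0.416). miR-592 had 74.7 ± 55.7 normalised reads in controls and 22.0 ± 22.1 after feed deprivation, and 1 of the feed-deprived goats had a single read. In the epithelial list, miR-215, with an unadjusted limma p of 0.103, reached 2008 normalised reads in feed-deprived replicate 2 and lay between 64.9 and 286 in the other 5.

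The 8 miRNAs that feed-deprived replicate 1 does not list are the last names of the other lists, whose order follows the p-values of a DESeq2 comparison. A lack of difference is therefore set by their place and tests nothing. Over the other 10 libraries exact permutation over 252 splits gave an adjusted p of 0.968 for each of the 8. They include miR-127, an abundant member of the DLK1-DIO3 cluster, at 96061 ± 21616 normalised reads in controls (SD, n = 5) and 97608 ± 29254 in the 5 remaining feed-deprived goats. Its log2 difference of 0.0082 lies near the low end of the cluster.

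The order of the deposited lists follows the p-values of a DESeq2 comparison of the groups. Over 627 miRNAs the Spearman correlation of position with DESeq2's p on the recovered reads was 0.99996, across miRNAs, which are not independent. The first 11 names stood in DESeq2's order, and the first 9 were the 9 that DESeq2 called at an adjusted p under 0.05.

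The DLK1-DIO3 cluster could appear higher through the scaling of the libraries, through 1 goat, or through a shift of all miRNAs with few reads. The scaling test decides nothing, because 1 factor per library moves all miRNAs nearly alike: the cluster median less that of the other miRNAs was 0.49 at its lowest and 0.50 at its highest over 4 scalings. The tables argue against the other explanations. The median with all libraries, 0.46, was lowest without feed-deprived replicate 4, at 0.30, and next without control replicate 2, at 0.32. It lay at percentile 100 of 10000 random lists matched on abundance, whose median was 0.015. Chance stays open for the lists: 31 of 100 splits of the goats gave at least the 3 lists of the real one, and the highest other split gave 5. The exact permutation p of the cluster mean was 0.0087 and its adjusted p over 16 lists 0.087. A response of the imprinted region to feed deprivation is a hypothesis that these values leave standing, and they do not establish it. For single miRNAs the count was not matched by the other splits drawn: 1 of 100 splits, the real one, gave 3 or more, and the highest other gave 2. Chance is thus less likely there but not excluded, since only 100 of the 462 splits were drawn. The count itself fell to 0 without feed-deprived replicates 1, 4 or 5 when the filter was rerun.

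If feed deprivation acted on the transcription of miRNA genes, both arms of a hairpin would be expected to change together. More immune cells or more blood in the fat would also move both arms, so arms that change together cannot tell these accounts apart. Over 29 hairpins with both arms tested, the log2 fold changes of the arms had Pearson r = 0.763 (permutation p = 1e-05, the smallest that 100000 permutations can give) and Spearman's rho = 0.706 (permutation p = 9e-05), and 21 had the same sign. Without the 2 hairpins farthest from the median, r was 0.816. These p-values come from random pairings of arms, whose 95th percentile of r was 0.313, and do not test feeding. Part of the correlation needs no feeding effect, since both arms share any difference between goats. Over the other 461 splits of the goats r had a median of 0.375, above that percentile. The real value lay above 97.6% of these splits, and only that figure bears on feeding. The values go with a shared change of both arms, as in miR-142 (0.79 and 1.02) and miR-21 (0.80 and 1.18). Of these arms only miR-142-5p passed the threshold on its own. An exception was miR-27a, whose 5p arm had 0.96 and whose 3p arm 0.0012.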
